A study of Homo sapiens with 6 samples.

How the data were processed

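The samples were L3.6pl cells, a human pancreatic cancer line, kept in culture medium with fetal calf serum and given no drug. The labels name 3 parental samples with wild-type ARID1A and 3 ARID1A-deficient samples, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, and libraries were made with a TruSeq version 2 kit that captures polyadenylated RNA. This kit does not mark strand, so reads of a gene and of an overlapping antisense gene are not separated.

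The authors deposited 1 table per sample with a gene symbol and an FPKM value, which is a fragment number scaled to transcript length in kilobases and to the mapped fragments of the library. Per the submitters' processing notes, TopHat2 2.1.1, Cuffnorm 2.2.1.2 and Cuffdiff 2.2.1.5 were used, with the human build GRCh37, also called hg19. The gene annotation, filters and scaling options are not given in the sources used here. Per the file headers, the samples titled replicates 1, 2 and 3 carry the numbers 1, 0 and 2 in both groups. An FPKM value is scaled to its library, by the total or by another factor, since the scaling options are not known. An overall change of RNA per cell is therefore not visible. The value also depends on the effective length used for each gene, which weighs most for short genes such as those of microRNAs and histones.

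Each table held 23273 rows with the same symbols in the same order. In 28 rows the symbol had been turned into a calendar date by a spreadsheet, and these were left out of every test. The gene TUBB was listed at 0 in all 6 libraries and RPS27 at 0.600 to 2.79 FPKM, so an exact 0 can be a failed estimate. Values of such rows are given per library, and no fold is given for a gene listed at 0 in any library. Total fragments are not given in the sources used here. The lowest values lie at multiples of what 1 fragment is worth, and the modal ratio of the low rows (under 0.2 FPKM in every library, bins of 0.05 on the log2 scale) was used to estimate each library's depth relative to parental library 1. If values were not scaled to the library's total, this ratio reflects the scaling factors used and not the depth itself. Precision per gene therefore rests on the spread between the 3 libraries of a group.

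Since FPKM values are not counts, limma 3.58.1 (R 4.3.3) was used with a mean-variance trend and robust variance moderation on log2(FPKM + 1), with group as the only term and all 6 libraries. Genes with a mean of at least 0.5 FPKM were tested, 12826 of 17832 rows above 0 in at least 1 library. P-values are two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Changes of at least 2-fold are called genes with an absolute log2 fold change of at least 1.

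For groups of genes, 28 lists were fixed before the data were examined. They cover SWI/SNF subunits, pancreatic cancer subtypes, mesenchymal and epithelial genes, interferon and antigen presentation, NF-kB, DNA repair, S phase, mitosis, p53, senescence, hypoxia, cholesterol, NRF2, aldehyde dehydrogenases, unfolded protein response, ERK, AP-1, YAP and TEAD, TGF-beta, ribosome biogenesis, ductal, acinar, leukocyte, fibroblast and endothelial, and histone genes. The 27 lists with at least 5 tested members entered camera with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry served as alternatives. Lists share members, such as CTGF and the collagen genes, so their tests are not independent.

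The genes named follow a rule that was also fixed before. It takes ARID1A, the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap and whose mean is at least 3 FPKM, and up to 4 members with the smallest adjusted p from each list that passed or had at least 3 called members. It adds ARID1B, SMARCA4, SMARCA2, CDH1, VIM, GATA6, KRT17, CDKN1A and MYC. Genes outside this rule are named as chosen after their values were seen, apart from genes at the ends of runs and the markers DCN, LUM, SPARC, FN1, COL6A1, COL6A2, COL6A3, BGN, TAP1, TAP2, PSMB8 and TUBB, which are given as background. A gene that the rule takes is not reported here. Older symbols are kept as deposited, such as IL8 for CXCL8, CTGF for CCN2 and CYR61 for CCN1.

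The annotation at hand was of build GRCh38, so no coordinates are given. Transcript lengths came from GENCODE transcripts by symbol, with a length for 96.0% of tested genes, and the order of genes along chromosomes came from a RefSeq table of GRCh38, with a place for 96.7%. Runs of neighbouring genes were sought after the data were examined. The median log2 fold change was taken in windows of 41 tested genes within a chromosome, and windows beyond the largest value that 5% of 1000 random gene orders reached were joined.

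The procedure was tested on simulated values for 12735 genes with the measured means and variances and 200 changed genes. The changed genes were drawn outside the lists from genes with a mean of at least 3 FPKM, so recovery of lower genes was not tested. The procedure recovered 32.8% of 1.5-fold, 82.1% of 2-fold and 98.5% of 4-fold changes, and 4.70% of its calls were of unchanged genes. A list with a planted shift was recovered with 0 others called, and a planted run of 80 genes was recovered whole together with 37 genes that lie within 1 window of it. The shift planted in that run was larger than the median shift of any run found in the data, the strongest of which was -0.378. Several of those runs also held fewer genes, so the search was not tried on runs as weak or as short. The noise was drawn independently for each gene. The simulation therefore does not show how these rates, the list test or the run search hold where genes vary together.

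Alternatives chosen before were median-ratio and trimmed-mean rescaling, no filter or a mean of at least 3 FPKM, a pseudocount of 0.1, limma without a trend, the replicate number as a block, and each library left out in turn. Added after the data were examined were a length covariate (each library's slope of log2 values on log2 transcript length), quantile normalization, and the removal of small RNA rows, of rows listed at 0 in any library, and of genes in shifted runs. Figures were drawn with matplotlib 3.10.9.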

Results

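Messenger RNA was profiled in L3.6pl, an established human pancreatic cancer cell line, in 3 parental libraries with intact ARID1A and 3 libraries from ARID1A-deficient cells, all without drug treatment. Each library gives 1 value per gene in FPKM, fragments scaled to transcript length and to the library, with scaling options that are not given. The values of the libraries summed to between 576084 and 792187 FPKM, and 15635 to 16391 rows were above 0. Total fragment numbers are not given in the sources used here. From the spacing of the lowest values, the depth relative to parental library 1 was estimated at 0.783 and 1.02 in parental libraries 2 and 3. It was 1.28, 0.729 and 0.797 in ARID1A-deficient libraries 1, 2 and 3. These estimates assume values scaled to the library's total. Pearson's r of log2 values across genes, which are not independent replicates, was 0.941 to 0.965 within a group and 0.919 to 0.943 between groups. The first principal component held 38.4% of the variance and separated the groups. Component 2 held 24.1% and did not separate them.

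ARID1A, the gene for a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, measured 11.8, 6.76 and 9.42 FPKM in the parental libraries and 3.55, 3.28 and 3.61 FPKM in the ARID1A-deficient libraries. The means were 9.32 ± 2.52 and 3.48 ± 0.179 FPKM (SD, n = 3 each), a log2 fold change of -1.18 (SE 0.18, limma adjusted p = 0.00610). The transcript was thus 2.68-fold lower and still measurable. The sample titles mark this group as ARID1Ako, that is, a knockout. How the gene was disrupted is not given in the sources used here, and a value per gene does not show whether the remaining transcripts encode the protein. ARID1A also lies in a stretch of 147 neighbouring genes, from LINC00339 to KIAA0319L, with a median log2 fold change of -0.26.

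The comparison addresses which transcripts differ between these ARID1A-deficient and parental cells. The labels do not say that the ARID1A-deficient samples came from several clones, and no sample restores ARID1A. Effects of ARID1A deficiency and other differences between the cells therefore cannot be told apart. MGP, COL1A2, COL3A1 and ALDH1A1 were among the largest increases, and MUC5B, LCN2, KRT13 and H19 among the largest decreases. MGP, which encodes matrix Gla protein, rose 184-fold from 0.864 ± 0.274 to 159 ± 12.8 FPKM, and COL1A2, a chain of type I collagen, rose 468-fold from 0.092 ± 0.0251 to 43.1 ± 0.842 FPKM (SD, n = 3 each). ALDH1A1, a retinaldehyde dehydrogenase, rose 499-fold from 0.144 ± 0.0524 to 72.1 ± 2.92 FPKM. MUC5B, a secreted gel-forming mucin, fell 99.6-fold from 11.9 ± 1.15 to 0.119 ± 0.0593 FPKM, and LCN2, the secreted lipocalin 2, fell 26.4-fold from 36.1 ± 6.81 to 1.37 ± 0.379 FPKM. A fold in FPKM is the ratio of the group means, and a log2 fold change is on the log2(FPKM + 1) scale, which understates the change of low genes. Parental values were 0.0888 to 0.193 FPKM for ALDH1A1 and 0.0642 to 0.113 FPKM for COL1A2. For MUC5B the ARID1A-deficient values were 0.0710 to 0.186 FPKM. Such low values in 1 group make the size of these folds imprecise.

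Of 12826 genes tested with limma, 2043 differed after Benjamini-Hochberg adjustment, 1003 higher and 1040 lower in ARID1A-deficient cells, or 15.9% of those tested. A change of at least 2-fold was met by 446 of them, 285 higher and 161 lower, and by 735 genes with a pseudocount of 0.1. All 3 libraries of one group lay on the same side of the other group for 35.3% of tested genes, where chance gives 10%. The number of changed genes depended on single libraries: it was 4113 without parental library 2, 1033 without parental library 3, and 1261, 1064 and 960 without ARID1A-deficient libraries 1, 2 and 3. With a minimum mean of 3 FPKM, 667 genes were higher. The number of changed genes was 4543 with each library's trend of values with transcript length as a covariate, and 1283 without genes of stretches of neighbours that shifted together, a set chosen after the data were examined. That slope on log2 transcript length was 0.0587, -0.0562 and 0.0266 in parental libraries 1, 2 and 3. In ARID1A-deficient libraries 1, 2 and 3 it was -0.00136, -0.0259 and -0.00194. Parental library 2 thus had the lowest slope and parental library 1 the highest.

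The other largest increases included SMR3B, a salivary secreted protein gene, at 0, 0.287 and 0.110 FPKM in the parental libraries and 56.6, 71.5 and 59.6 FPKM in the ARID1A-deficient libraries. PI3, which encodes the protease inhibitor elafin, rose 52.8-fold (log2 fold change 5.26, SE 0.27). COL3A1, the chain of type III collagen, rose 43.4-fold from 2.14 ± 0.255 to 92.9 ± 5.32 FPKM, and SRGN, the proteoglycan serglycin, rose 51.3-fold from 0.844 ± 0.166 to 43.3 ± 2.50 FPKM (SD, n = 3 each). CALB2, which encodes the calcium-binding protein calretinin, rose 30.5-fold to 142 ± 12.1 FPKM. FOXJ1, a transcription factor of motile cilia formation, rose 30.0-fold to 71.7 ± 8.29 FPKM. The row for MIR200A was listed at 0 in every parental library and at 29.8, 52.1 and 47.7 FPKM in the ARID1A-deficient libraries. The limma adjusted p of these genes lay between 1.10e-06 for COL3A1 and 5.33e-05 for PI3.

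Among the largest decreases, KRT13, a keratin of stratified epithelium, fell 11.5-fold from 300.0 ± 52.4 to 26.2 ± 2.66 FPKM (SD, n = 3 each). The imprinted noncoding RNA H19 fell 9.06-fold from 605 ± 64.6 to 66.7 ± 8.12 FPKM. TNFAIP2, a gene induced by tumour necrosis factor, fell 12-fold from 47.3 ± 3.09 to 3.93 ± 0.421 FPKM. MB, which encodes myoglobin, measured 20.4, 29 and 22.2 FPKM in parental libraries and 0.235, 0 and 0.764 FPKM in ARID1A-deficient libraries. SLC16A5, a monocarboxylate transporter gene, measured 9.51, 11.6 and 10.5 FPKM against 0, 0.0521 and 0 FPKM. The pseudogene HNRNPA1P10, which may share reads with HNRNPA1, measured 6.06, 11.3 and 10.0 FPKM against 0.00233, 0 and 0 FPKM. Rows for MIR4258, at 73.0, 45.8 and 35.7 FPKM, and MIR600, at 40.5, 5.72 and 19.2 FPKM, were listed at 0 in every ARID1A-deficient library. A microRNA precursor is very short for a poly(A) library, a listed 0 can be a failed estimate, and the MIR600 call (adjusted p = 0.0156) ended without parental library 3 or any single ARID1A-deficient library (highest adjusted p = 0.0768).

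**Figure D1:**
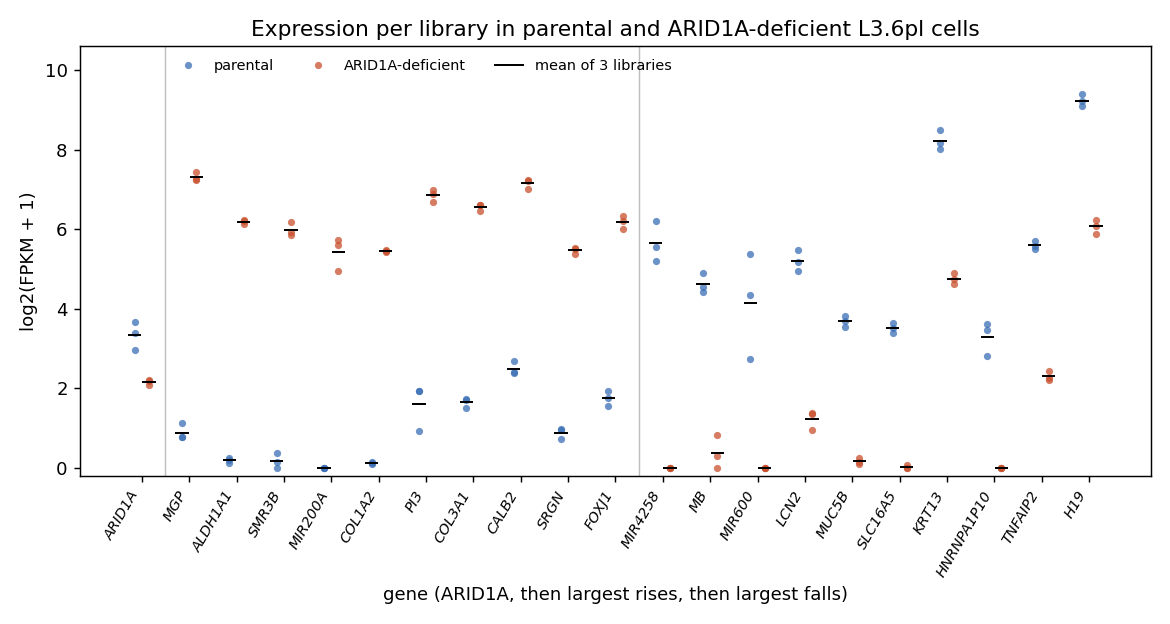
Expression of ARID1A, the 10 genes with the largest increases and the 10 with the largest decreases, 1 point per library on the y axis in log2(FPKM + 1), with parental libraries in blue and ARID1A-deficient libraries in orange and a bar at the mean of 3 libraries. ARID1A lies between 6.76 and 11.8 FPKM in parental libraries and between 3.28 and 3.61 FPKM in ARID1A-deficient libraries. The groups do not overlap for any gene drawn, which the rule for choosing the genes required of all but ARID1A.

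Mesenchymal and matrix genes had 11 of 17 tested members higher, 3 lower and 3 not past the threshold. The lower count was 0, with 8 higher, without parental library 3 or without ARID1A-deficient library 2 or 3. MMP2, a secreted gelatinase, rose 9.68-fold from 5.53 ± 0.763 to 53.5 ± 2.99 FPKM, and CDH2, which encodes N-cadherin, rose 49.9-fold from 0.0909 ± 0.0579 to 4.53 ± 0.601 FPKM (SD, n = 3 each). The size of the CDH2 fold is imprecise, since its parental values were 0.0786, 0.0402 and 0.154 FPKM. COL1A2 and COL3A1 were the other members with the smallest adjusted p, and COL3A1 lies in a stretch of neighbouring genes that shifted higher. The members named for the smallest adjusted p all rose, so they do not represent the 3 that fell. The list was fixed with 28 genes, of which 17 reached the mean needed for testing. VIM, the mesenchymal intermediate filament gene vimentin, measured 753 ± 85.4 and 908 ± 50.9 FPKM and did not pass (adjusted p = 0.328), but did with quantile normalization and with the length covariate. The members past the threshold adjusted over the list alone were 11 higher and 3 lower. The list passed camera with an adjusted p = 1.24e-05, and adjusted p = 0.11 with an estimated correlation.

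Markers of fibroblasts and endothelium, 2 cell types that a pure line should not hold, were measurable for 7 genes. Of these, 3 rose, 1 fell and 3 did not pass, and the 3 that rose are COL1A2, COL3A1 and COL1A1, which are also in the mesenchymal list. COL1A1 rose 2.14-fold from 20.9 ± 1.74 to 44.7 ± 5.36 FPKM (SD, n = 3 each). PECAM1, an endothelial adhesion gene, fell 1.63-fold (adjusted p = 0.0254), a call that ended with any single library but parental 2 left out (highest adjusted p = 0.0992). The fibroblast genes DCN and LUM were listed at 0 in every library, and SPARC, an abundant fibroblast transcript, reached 0.291 FPKM at most in ARID1A-deficient cells. Past the threshold were 4 higher and 1 lower when adjusted over the list alone. The list passed camera (adjusted p = 0.00741, and adjusted p = 0.171 with an estimated correlation). It did not pass without parental library 2 (adjusted p = 0.0541), with no filter on low values (adjusted p = 0.0543) or without genes of shifted stretches (adjusted p = 0.104). Among leukocyte markers, 3 were measurable, with 1 higher and 1 lower (0 lower without parental library 1 or 3 or ARID1A-deficient library 1 or 3), too few for a list test, and 5 acinar genes were measurable. None of the acinar genes passed limma (1 lower without parental library 2 and 1 higher without ARID1A-deficient library 1), with 1 higher and 1 lower at an unadjusted p under 0.05, and the camera adjusted p was 0.805.

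Inflammatory genes under NF-kB control rose in part and fell in part. Of 20 tested members, 11 rose, 2 fell (4 without parental library 2) and 7 did not pass. ICAM1, an adhesion molecule for leukocytes, rose 26.3-fold from 0.163 ± 0.0874 to 4.28 ± 0.127 FPKM, and IL8, a neutrophil chemokine, rose 6.25-fold from 1.39 ± 0.152 to 8.66 ± 0.721 FPKM (SD, n = 3 each). The members that fell were LCN2 and TNFAIP2, which are among the largest decreases of all genes. Adjusted over the list alone, 12 were higher and 3 lower. The camera adjusted p was 0.000139, and adjusted p = 0.11 with an estimated correlation. Of the 20 members, 5 lie in shifted stretches of neighbours.

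Interferon-stimulated genes had 6 of 25 tested members higher, 1 lower and 18 not past the threshold. Only 3 were higher without ARID1A-deficient library 2 or 3, and the lower count was 3 without parental library 2 and 0 without parental library 3 or any single ARID1A-deficient library. ISG20, an exonuclease gene, rose 3.48-fold from 9.18 ± 3.32 to 32 ± 5.86 FPKM (SD, n = 3 each). IFIT1, an RNA-binding antiviral gene, rose 1.81-fold (adjusted p = 0.00511), and MX1, an antiviral GTPase gene, rose 2.43-fold (adjusted p = 0.0111). IRF9, a transcription factor of the interferon response, rose 1.53-fold (adjusted p = 0.0154), although its neighbours shifted lower. Its call ended without parental library 3 or without ARID1A-deficient library 2 or 3 (highest adjusted p = 0.0780). The members past the threshold adjusted over the list alone were 6 higher and 2 lower. The list passed camera (adjusted p = 0.00919, and adjusted p = 0.271 with an estimated correlation), but not without parental library 2 (adjusted p = 0.0541), with a minimum mean of 3 FPKM (adjusted p = 0.0747) or without genes of shifted stretches (adjusted p = 0.0673). Antigen presentation genes were measurable for 6 of 20 members, and none passed limma, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.477). TAP1, TAP2 and PSMB8, which belong to that list, were listed at 0 in all 6 libraries, as was TUBB, a tubulin gene that cells generally express.

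Factors secreted by senescent cells rose for 8 of 16 tested members, with 3 lower and 5 not past the threshold. CTGF, a matricellular growth factor that also belongs to the YAP and TGF-beta lists, rose 5.63-fold from 4.45 ± 0.433 to 25 ± 2.45 FPKM, and lies in a stretch that shifted higher. PLAU, the urokinase gene, rose 2.05-fold from 31.3 ± 1.28 to 64.1 ± 3.38 FPKM (SD, n = 3 each). IGFBP3, an insulin-like growth factor carrier, fell 2.92-fold, and PLAT, the tissue plasminogen activator gene, fell 1.86-fold. Past the threshold were 9 higher and 3 lower when adjusted over the list alone. The camera adjusted p was 0.00772, and adjusted p = 0.285 with an estimated correlation. Without genes of shifted stretches the list did not pass (adjusted p = 0.0671).

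Target genes of p53 rose for 5 of 22 tested members, with 1 lower and 16 not past the threshold. CDKN1A, an inhibitor of cyclin-dependent kinases, rose 2.44-fold from 4.17 ± 0.546 to 10.2 ± 0.929 FPKM (SD, n = 3 each). TP53INP1 rose 3.13-fold, PLK3, a stress-response kinase gene, rose 2.03-fold, and BBC3, which encodes the pro-apoptotic protein PUMA, rose 1.99-fold. The BBC3 call ended without ARID1A-deficient library 1 or 2 (highest adjusted p = 0.0659). The count of higher members was 3 without ARID1A-deficient library 1 or 2, and that of lower members was 3 without parental library 2 and 0 without any other single library. Adjusted over the list alone, 8 were higher and 1 lower. The camera adjusted p was 0.00772, and adjusted p = 0.171 with an estimated correlation.

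Genes of S phase and E2F control had 6 of 28 tested members lower, none higher in the limma test and 22 not past the threshold. The count depended on single libraries, with 11 lower without parental library 2, 1 without parental library 3, and 2 and 1 without ARID1A-deficient libraries 2 and 3. It was 19 of 28 with the length covariate and 3 of 23 without genes of shifted stretches. E2F2, an E2F transcription factor, fell 1.73-fold from 5.72 ± 0.590 to 3.30 ± 0.464 FPKM, and MCM6, a subunit of the replicative helicase, fell 1.47-fold from 67.3 ± 3.89 to 45.7 ± 0.800 FPKM (SD, n = 3 each). RRM2, a ribonucleotide reductase subunit, fell 1.45-fold and PRIM1, a primase subunit, fell 1.40-fold. E2F2 and RRM2 lie in stretches of neighbours that shifted lower. The E2F2 call ended without ARID1A-deficient library 1 or 2 (highest adjusted p = 0.0617). The calls of MCM6, PRIM1 and RRM2 ended without parental library 3 or ARID1A-deficient library 3, and that of RRM2 also without ARID1A-deficient library 2 (highest adjusted p = 0.0534, 0.0688 and 0.0655). The members past the threshold adjusted over the list alone were 8 lower and 0 higher, and 14 were lower and 0 higher at an unadjusted p under 0.05. The camera adjusted p was 2.79e-05, and adjusted p = 0.11 with an estimated correlation. Mitosis genes had 1 of 28 members lower (0 adjusted over the list alone, and 4 at an unadjusted p under 0.05). Without parental library 2 that was 8 lower and 1 higher, and 0 without parental library 3 or any single ARID1A-deficient library. They did not pass camera (adjusted p = 0.0825), but did without parental library 2 (adjusted p = 0.0190), without ARID1A-deficient library 1 (adjusted p = 0.0343) and with no filter on low values (adjusted p = 0.0279).

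Replication-dependent histone genes had 8 of 14 tested members higher, none lower in the limma test and 6 not past the threshold. This fell to 4 higher without parental library 3 and to 3 without ARID1A-deficient library 2 or 3. HIST1H2AC rose 3.67-fold from 6.28 ± 0.439 to 23.0 ± 4.28 FPKM, and HIST1H2BD rose 2.31-fold from 14.1 ± 4.48 to 32.7 ± 4.29 FPKM (SD, n = 3 each). HIST2H2BE rose 2.09-fold and HIST1H2BK rose 1.87-fold. The calls of HIST1H2BD and HIST1H2BK ended without ARID1A-deficient library 2 or 3, and that of HIST1H2BK also without parental library 3 (highest adjusted p = 0.0561 and 0.0567). Histone genes have near-identical copies, so reads may have been divided among them, and most of their transcripts carry no poly(A) tail. Past the threshold were 10 higher and 0 lower when adjusted over the list alone, and likewise at an unadjusted p under 0.05. The camera adjusted p was 2.79e-05, and adjusted p = 0.177 with an estimated correlation.

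Genes of homologous recombination and DNA damage repair had 4 of 29 tested members lower, none higher and 25 not past the threshold in the limma test. It was 14 lower and 1 higher without parental library 2, and 2 lower without parental library 3 or any single ARID1A-deficient library. BRCA1, a recombination mediator, fell 1.84-fold from 17.1 ± 1.99 to 9.33 ± 0.397 FPKM, and EXO1, an end-resection nuclease, fell 1.62-fold from 12.8 ± 0.986 to 7.90 ± 0.217 FPKM (SD, n = 3 each). RAD51D, a recombination gene, fell 1.45-fold and FANCA, a Fanconi anaemia core gene, fell 1.29-fold. BRCA1 and RAD51D lie in stretches that shifted lower. The FANCA and RAD51D calls ended without parental library 3 or any single ARID1A-deficient library, and that of RAD51D also without parental library 1 (highest adjusted p = 0.144 and 0.142). Adjusted over the list alone, 5 were lower and 0 higher, and 8 were lower and 1 higher at an unadjusted p under 0.05. The list passed camera (adjusted p = 0.00173, and adjusted p = 0.578 with an estimated correlation), but not fry's directional test (adjusted p = 0.0565).

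Aldehyde dehydrogenases split between ALDH1A1, the single member that rose (2 without parental library 2), and 5 of 15 tested members that fell. ALDH3B1 fell 5.70-fold from 21.4 ± 2.01 to 3.75 ± 0.313 FPKM, and ALDH1A2, another retinaldehyde dehydrogenase, fell 3.92-fold from 3.08 ± 0.563 to 0.786 ± 0.135 FPKM (SD, n = 3 each). ALDH3A2, which oxidizes fatty aldehydes, fell 1.58-fold and lies in a stretch that shifted lower. The members past the threshold adjusted over the list alone were 1 higher and 6 lower. The tests differ in sign: camera placed the list lower (adjusted p = 0.0213, and adjusted p = 0.181 with an estimated correlation), and fry's directional test placed it higher (adjusted p = 0.00326), while the median was -0.46 and the mean -0.07. With a minimum mean of 3 FPKM the camera adjusted p was 0.0762.

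Markers of the classical and basal-like subtypes of pancreatic cancer moved in both directions. In the classical list, 3 of 9 tested members rose, 3 fell and 3 did not pass. TFF2, a secreted trefoil factor, fell 8.77-fold from 50.6 ± 13.5 to 5.78 ± 1.1 FPKM, while CEACAM6, an adhesion gene, rose 6.67-fold from 2.37 ± 0.445 to 15.8 ± 0.958 FPKM (SD, n = 3 each). TSPAN8, a tetraspanin gene, rose 3.29-fold and ST6GALNAC1, a sialyltransferase gene, rose 3.04-fold. GATA6, a transcription factor of the classical subtype, measured 9.48 ± 0.515 and 10.2 ± 1.21 FPKM and did not pass (adjusted p = 0.599). In the basal-like list, 4 of 12 rose, 3 fell and 5 did not pass. KRT6A, a keratin with near-identical paralogs, rose 10.1-fold from 1.83 ± 0.511 to 18.4 ± 1.53 FPKM, and FGFBP1, a secreted carrier of fibroblast growth factors, rose 6.18-fold from 155 ± 22.9 to 960 ± 42.5 FPKM although its neighbours shifted lower. FAM83A fell 4.68-fold. KRT17, a basal keratin, measured 2117 ± 619 and 2281 ± 322 FPKM and did not pass (adjusted p = 0.788). Past the threshold were 4 higher and 3 lower in either list when adjusted over the list alone. The camera adjusted p was 0.293 for the classical and 0.426 for the basal-like list, and the basal-like list passed with a minimum mean of 3 FPKM (adjusted p = 0.0394).

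Target genes of YAP and TEAD rose for 8 of 23 tested members and fell for 4, and the list did not pass camera (adjusted p = 0.194), except without ARID1A-deficient library 2 (adjusted p = 0.0392). CYR61, a matricellular gene, rose 5.70-fold from 16.5 ± 0.929 to 93.8 ± 4.10 FPKM, and ANKRD1 rose 7.98-fold from 3.35 ± 0.301 to 26.8 ± 1.72 FPKM (SD, n = 3 each). NT5E, which encodes the ectonucleotidase CD73, rose 6.66-fold. Of 16 TGF-beta targets, 3 rose and 3 fell (camera adjusted p = 0.477). SMAD7, an inhibitor of TGF-beta signalling, fell 2.46-fold, and NOG, which encodes the BMP antagonist noggin, rose 2.48-fold. PMEPA1 rose 1.29-fold, a call that ended with any single library but parental 2 left out (highest adjusted p = 0.110). Lower YAP and TEAD targets numbered 2 and 1 without ARID1A-deficient libraries 2 and 3, and lower TGF-beta targets 1 without parental library 3 or ARID1A-deficient library 1 or 3. Adjusted over the list alone, 9 were higher and 6 lower for YAP and TEAD, and 4 higher and 4 lower for TGF-beta.

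Immediate early and ERK-dependent genes also split. FOS, an AP-1 subunit, fell 4.46-fold from 77.6 ± 6.52 to 17.4 ± 1.36 FPKM, while SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, rose 3.52-fold from 17.2 ± 2.22 to 60.5 ± 3.10 FPKM (SD, n = 3 each). LIF, a cytokine of the interleukin 6 family, rose 3.08-fold, and HBEGF, a ligand of the EGF receptor, rose 1.93-fold in a stretch that shifted higher. MYC fell 1.29-fold from 109 ± 1.61 to 84.3 ± 2.87 FPKM (adjusted p = 0.0417). Of 20 ERK output genes, 5 rose and 3 fell (camera adjusted p = 0.417; adjusted over the list alone, 6 and 4), with 6 lower without parental library 2. Of 14 AP-1 factors, 1 rose and 3 fell (camera adjusted p = 0.979; adjusted over the list alone, 2 and 3), with 3 higher without parental library 2. FOSL2 fell 2.79-fold in a stretch that shifted lower, MAFF rose 2.15-fold and JUN fell 1.36-fold. The calls of MYC and JUN ended with any single library but parental 2 left out (highest adjusted p = 0.176 and 0.109), and that of MYC also without genes of shifted stretches.

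Of 26 tested SWI/SNF subunits, ARID1A fell, PHF10 and SMARCD1 rose and 23 did not pass (camera adjusted p = 0.873). PHF10, a subunit of the PBAF form of the complex, rose 1.51-fold from 21.7 ± 1.66 to 32.7 ± 0.755 FPKM (SD, n = 3 each), in a stretch that shifted higher. SMARCD1 rose 1.22-fold (adjusted p = 0.0441), a call that ended with any single library but parental 2 left out (highest adjusted p = 0.181), in limma without a trend and without genes of shifted stretches. ARID1B, the paralog of ARID1A, measured 5.57 ± 1.56 and 6.13 ± 0.604 FPKM and did not pass (adjusted p = 0.666), but did with the length covariate (adjusted p = 0.0297), and it lies in a stretch that shifted higher. The ATPase genes measured 39.7 ± 1.0 and 40.7 ± 2.05 FPKM for SMARCA4 (adjusted p = 0.824), and 7.29 ± 1.47 and 7.62 ± 1.05 FPKM for SMARCA2 (adjusted p = 0.833). SMARCD2 was 1.16-fold lower in the group means and did not pass (adjusted p = 0.204), but did with the length covariate. The members past the threshold adjusted over the list alone were 1 higher and 1 lower, and without parental library 2 the limma test gave 3 higher and 2 lower.

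Epithelial junction genes were measurable for 26 members, of which 3 rose, 1 fell and 22 did not pass (camera adjusted p = 0.914). CLDN4, a claudin of tight junctions, rose 3.62-fold from 5.42 ± 0.111 to 19.7 ± 1.99 FPKM, and CLDN1 rose 2.57-fold from 55.3 ± 5.79 to 142 ± 6.86 FPKM (SD, n = 3 each). CLDN3 rose 1.98-fold and ESRP1, an epithelial splicing regulator, fell 1.33-fold, and both calls ended with any single library but parental 2 left out (highest adjusted p = 0.0877 and 0.185). ESRP1 (adjusted p = 0.0492) also lost its call with a trimmed-mean or quantile scaling, with other filters, in limma without a trend and without genes of shifted stretches. CDH1, which encodes E-cadherin, measured 5.35 ± 0.991 and 3.67 ± 0.279 FPKM and did not pass (adjusted p = 0.0838), but did without parental library 2, with quantile normalization and with the length covariate. Without parental library 2, 4 junction genes were lower; it was 3 in limma without a trend, 7 higher and 8 lower with the length covariate, and 4 higher and 5 lower with quantile normalization. Of 9 ductal genes, 3 rose and 2 fell (camera adjusted p = 0.476), with 1 lower without parental library 3 or ARID1A-deficient library 2 or 3. SPP1, which encodes osteopontin, rose 4.94-fold from 8.46 ± 0.360 to 41.8 ± 0.215 FPKM, and the transcription factor genes FOXA2 and SOX9 rose 2.53-fold and 1.94-fold. Past the threshold were 3 higher and 0 lower for junction genes, and 4 higher and 3 lower for ductal genes when adjusted over the list alone.

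Metabolic and stress lists did not pass camera. Among 28 hypoxia and glycolysis genes, 4 rose and 4 fell (camera adjusted p = 0.310; adjusted over the list alone, 4 and 6), but 1 rose without parental library 3 or ARID1A-deficient library 2 or 3. That list passed fry's directional test, which placed it lower (adjusted p = 0.0130). CA9, a carbonic anhydrase gene induced by hypoxia, fell 8.58-fold from 10.7 ± 2.77 to 1.25 ± 0.0315 FPKM (SD, n = 3 each), although its neighbours shifted higher. EGLN3, a prolyl hydroxylase gene, fell 2.57-fold in a stretch that shifted lower, and NDRG1 fell 2.30-fold. SLC2A3, a glucose transporter gene, measured 0, 0.0224 and 0.0172 FPKM in parental libraries and 1.5, 1.49 and 1.56 FPKM in ARID1A-deficient libraries. Among 23 NRF2 and glutathione genes, 5 rose and 2 fell (camera adjusted p = 0.293; adjusted over the list alone, 7 and 3), with 10 and 4 without parental library 2 and 3 and 2 without ARID1A-deficient library 2. AKR1C3 and AKR1C1, aldo-keto reductase genes that may share reads with close paralogs, rose 3.26-fold and 3.01-fold, SRXN1, which encodes sulfiredoxin, rose 1.52-fold and ABCC3, an organic anion exporter gene, fell 1.53-fold. Among 27 unfolded protein response genes, CHAC1 rose 1.53-fold, PPP1R15A rose 1.58-fold and PSAT1, a serine synthesis gene, fell 1.39-fold (camera adjusted p = 0.873 for the list; adjusted over the list alone, 1 and 0), and without parental library 2 it was 4 higher and 3 lower. Those calls ended without parental library 3 or ARID1A-deficient library 2 or 3, those of CHAC1 and PSAT1 also without parental library 1, and that of PSAT1 also without ARID1A-deficient library 1 (highest adjusted p = 0.127, 0.0655 and 0.194), with quantile normalization and without genes of shifted stretches. ASNS, which encodes asparagine synthetase, measured 394 ± 48.1 and 288 ± 7.52 FPKM without passing (adjusted p = 0.0910), but passed in limma without a trend, with quantile normalization and with the length covariate. Cholesterol synthesis genes had 1 of 24 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.206). This was 6 and 2 without parental library 2, and 0 and 1 without parental library 3 or any single ARID1A-deficient library. Ribosome biogenesis and MYC genes had 2 of 25 lower, and 0 adjusted over the list alone (camera adjusted p = 0.737), with 4 higher and 3 lower without parental library 2, 1 lower without parental library 1 and 0 without any of the other 4 libraries.

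**Figure D2:**
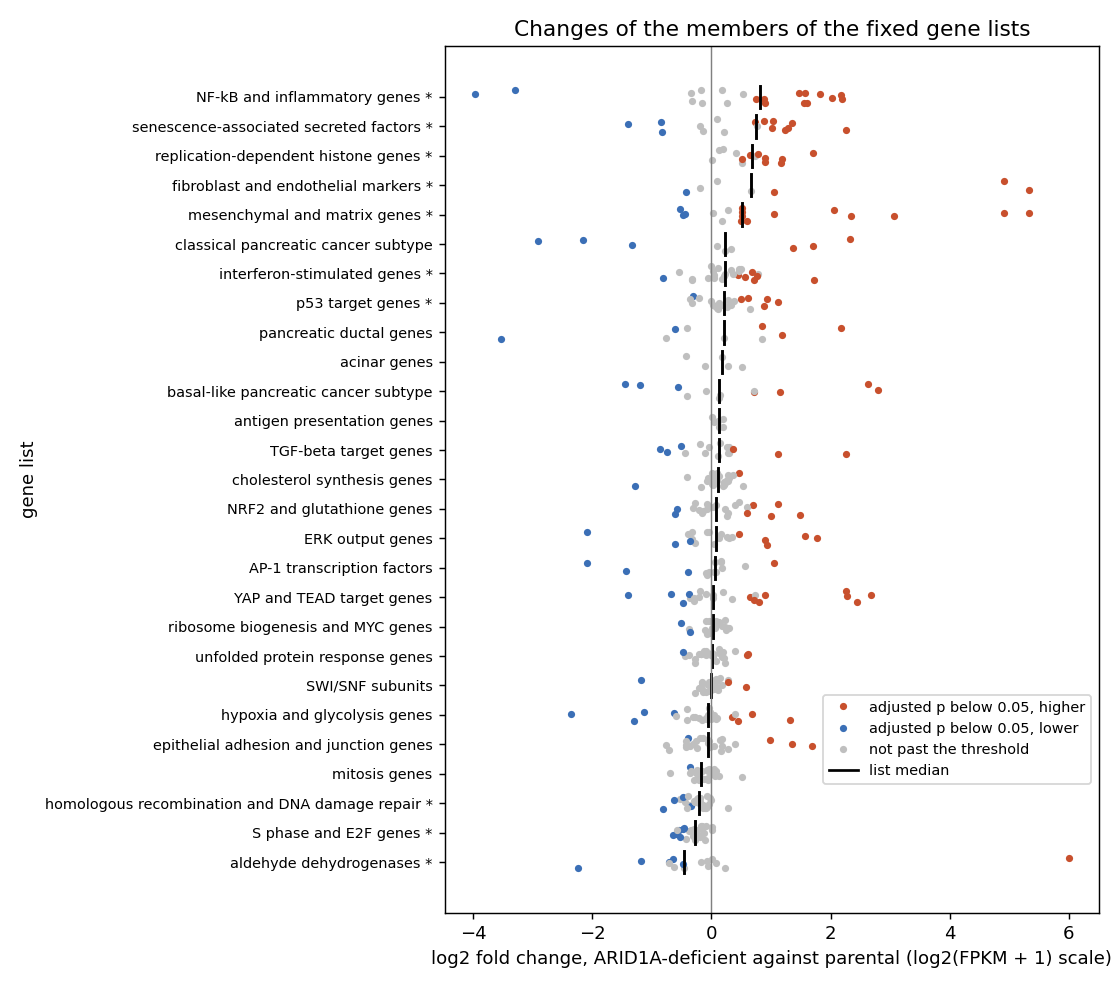
Log2 fold change of each tested member of the 27 lists with at least 5 tested members, on the x axis, with 1 row per list on the y axis ordered by the list median (black bar), members past the adjusted threshold of 0.05 in orange where higher and blue where lower, and an asterisk after lists past camera. The medians of the NF-kB and histone lists lie at 0.81 and 0.69 and that of the S phase list at -0.28, and ALDH1A1 stands alone at 6.00 among the aldehyde dehydrogenases.

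Counts of past-threshold members in the remaining lists also moved by over 1.5 times with other settings. With the length covariate, lower members numbered 9 for recombination, 8 for aldehyde dehydrogenases, 9 for hypoxia, 9 for mitosis (and 1 higher), 7 for YAP and TEAD, 4 for NF-kB, 5 for NRF2, 4 for ductal genes, 6 for the unfolded protein response and 1 for acinar genes. Higher members numbered 10 for p53, and higher and lower members 10 and 3 for interferon, 8 and 7 for ERK output, 7 and 2 for cholesterol synthesis, 4 and 2 for SWI/SNF, 3 and 3 for ribosome biogenesis and 2 and 3 for AP-1. Quantile normalization gave 7 lower for recombination, 8 higher for p53, 4 lower for ductal genes, 1 higher and 2 lower for mitosis, 2 higher for ribosome biogenesis and for AP-1, 2 lower for interferon and 0 lower for leukocyte markers. A minimum mean of 3 FPKM left 7 higher for NF-kB, 3 higher for interferon, NRF2 and p53 (with 0 lower for p53), 1 lower for the basal-like subtype and 0 lower for TGF-beta and fibroblast markers. With no filter on low values, 5 were higher for the classical subtype and for TGF-beta, 2 for acinar genes, and 0 lower for interferon. Leaving out genes of shifted stretches, 2 were lower for recombination and hypoxia, 1 for TGF-beta and ductal genes, and 0 for interferon, mitosis, p53, cholesterol synthesis, ribosome biogenesis, SWI/SNF, junction and unfolded protein response genes, and 3 were higher for ERK output and 0 for SWI/SNF and leukocyte genes. Limma without a trend gave 2 lower for the unfolded protein response, and trimmed-mean scaling and the removal of small RNA rows or of rows listed at 0 each gave 2 higher for AP-1.

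Of 27 lists tested, 10 passed camera with a preset correlation, 7 higher and 3 lower. With an estimated correlation 0 passed in camera, with 7 at an unadjusted p under 0.05, and 15 passed fry's directional test, which does not compare a list with other genes. The estimate lay below the preset 0.01 for the S phase (-0.0158), NF-kB (-0.0420), p53 (-0.0424), fibroblast (-0.0633) and aldehyde dehydrogenase (-0.0508) lists. A larger correlation therefore does not account for their higher p-values. Among the other lists past camera it ranged from 0.0354 for mesenchymal genes to 0.304 for recombination. Besides hypoxia, placed lower, some lists passed fry's directional test without passing camera, and fry placed them higher. These were the ductal (fry adjusted p = 0.00871), classical (0.00999), YAP and TEAD (0.0130), TGF-beta (0.0137) and basal-like (0.0254) lists. The median, mean or camera direction differed in sign for the classical subtype, ductal, junction, AP-1, SWI/SNF and unfolded protein response lists, which did not pass camera. Genes at an unadjusted limma p under 0.05 numbered 3781. The labels call the samples triplicates and do not say that they came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.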

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

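The look at rows outside the tested table was made after the data were examined. Among 28 rows whose symbols had been turned into dates, 25 were above 0 in at least 1 library. The row named 4-Mar stood out because every ARID1A-deficient library lay above every parental library, with a lowest ARID1A-deficient value of 0.702 FPKM against a highest parental value of 0.0154 FPKM. It was the 1 row of the 28 that separated in that direction, and chance gives 5% per row. The gene behind the date was not assigned here.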

How the results depend on the processing

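The covariate for transcript length, quantile normalization and the removal of rows or runs were chosen after the data were examined, as was the look at other splits. Of 10 splits of the 6 libraries into 3 and 3, 1, the real one, called 2043 genes and the highest of the others called 4, and 10 splits are too few for a share under 0.05. Every other split mixes the groups, so the group difference enters its residual spread and lowers its calls. Those counts are therefore no null level for the 2043. ARID1A kept its direction and call in every alternative that could test it (log2 fold change -1.37 to -1.01 with 1 library left out); it has no value once genes of shifted runs are removed. Of 116 other named genes, 1328 of 1351 values under alternatives other than leaving out a library kept direction and side of the threshold, 12 lost the call, 11 gained one and 0 changed sign; with 1 library left out it was 611 of 696, 79, 1 and 5. Calls of 21 of 108 named genes ended without some library, none of them without parental library 2. Most named genes were chosen for large changes or small adjusted p in the main fit, so their stability follows in part from that choice. It is no measure of the stability of the other called genes. The sign changes were in genes that had not passed: KRT17 ranged from -0.0317 (without parental library 1) to 0.36, ARID1B from -0.0494 (without parental library 2) to 0.30, SMARCA2 from -0.0835 (without parental library 2) to 0.17, with -0.02 without ARID1A-deficient library 1, and SMARCA4 from -0.00272 (without ARID1A-deficient library 3) to 0.0669. With 1 library left out, changed genes ranged from 960 (ARID1A-deficient library 3) to 4113 (parental library 2), higher genes from 522 to 2009, lower genes from 438 to 2104, genes changed at least 2-fold from 440 to 510 and lists past camera from 9 to 11. A minimum mean of 3 FPKM, which tests fewer genes, gave 667 higher genes, and a pseudocount of 0.1, which enlarges changes of low genes, gave 735 genes changed at least 2-fold. The length covariate gave 4543 changed genes, 2037 higher and 2506 lower. Parental library 2, whose removal also raised the count, had the lowest length slope (-0.0562). Parental library 1 had the highest (0.0587), and 1582 genes changed without it. Whether these slopes are the cause was not tested. Without genes of shifted runs, fewer genes were tested and 1283 changed, 567 of them lower, and 55.8% of calls were higher, against 49.1% with them. With the replicate number as a block, 4049 genes changed, 1861 higher and 2188 lower, and mitosis genes passed camera (adjusted p = 0.0314). Lower members numbered 14 for S phase, against 6, and 8 for junction genes, against 1. Among other lists, they numbered 9 for recombination, against 4, and 8 for hypoxia, against 4. For ERK output they numbered 7, against 3, and for mitosis 5, against 1. Higher members numbered 11 for interferon, against 6, and 7 for cholesterol synthesis, against 1. The deviations of same-numbered libraries correlated at 0.22, 0.22 and -0.01 across genes. Parental libraries 1 and 2 each correlated best with the ARID1A-deficient library of their number and parental library 3 with ARID1A-deficient library 1, a hint from the data and not the design. Since the third pair does not deviate together and the labels name no shared batch, the number was not taken as a pairing. With an estimated correlation 0 lists passed, against 10 by camera with the preset one and 15 by fry. Of 536 list values, 487 kept direction and side of the threshold, 19 lost and 12 gained the call, and 18 changed sign. Among lists past camera that was the aldehyde dehydrogenases under fry (adjusted p = 0.00326); the cause was not tested. The others were not past camera. AP-1 factors changed sign at an adjusted p of 0.904 (no filter), 0.997 (block), 0.973, 0.688 and 0.985 (without parental library 1, parental library 2 or ARID1A-deficient library 1; range 0.659 to 0.985 over the libraries left out), 0.977 (length covariate), 0.800 (quantile) and 0.875 (runs removed). SWI/SNF subunits did so at 0.904 (no filter), 0.847 (without parental library 2; range 0.687 to 0.918) and 0.966 (runs removed), and junction genes at 0.887 and 0.996 (without parental library 1 or ARID1A-deficient library 2) and 0.0950 (fry). Acinar genes did so at 0.916 without parental library 2 (range 0.401 to 0.955), and unfolded protein response genes at 0.754 and 0.985 without parental library 2 or ARID1A-deficient library 1 (range 0.595 to 0.985). The count test foreseen on recovered fragments was not run, since the steps of FPKM values depend on effective gene lengths that are not given in the sources used here, and those foreseen for count tables did not apply. Unknown total depth limits what can be said of genes near 0.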

Other observations

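The tests of random gene order, of held-out neighbours and of fibroblasts, and the window of 41 genes, were chosen after the patterns were seen, while those of histone genes and of the length covariate on runs were set before their values were seen. Further genes with large changes fall outside the lists and were chosen after their values were seen. Among genes lower in ARID1A-deficient cells, S100P, a calcium-binding protein gene, fell 8.97-fold from 1328 ± 465 to 148 ± 18.4 FPKM, S100A14 fell 8.41-fold from 311 ± 81.2 to 36.9 ± 2.25 FPKM, and AQP3, an aquaporin gene, fell 4.50-fold from 582 ± 17.3 to 129 ± 7.41 FPKM (SD, n = 3 each). The epithelial transcription factor gene ELF3 fell 5.34-fold, CDH3, which encodes P-cadherin, fell 5.44-fold and TRIM29 fell 7.35-fold. S100P lies in a stretch of neighbours that shifted lower and AQP3 in one that shifted higher.

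Genes that rose included EFEMP1, a fibulin of the extracellular matrix, which rose 11-fold from 18.4 ± 2.16 to 202 ± 12 FPKM although its neighbours shifted lower (SD, n = 3 each). MFAP5, a microfibril component, rose 25.7-fold to 25.5 ± 2.56 FPKM, and SERPINA3, a protease inhibitor gene, rose 47.7-fold to 11.2 ± 0.902 FPKM. CYP24A1, which inactivates vitamin D, rose 34.7-fold to 22.2 ± 2.22 FPKM. EDN1, which encodes the peptide endothelin 1, rose 22.7-fold to 8.37 ± 1.26 FPKM, and TEAD2, a transcription factor partner of YAP, rose 24.4-fold to 13.0 ± 1.78 FPKM. All 12 genes passed limma with every library left out in turn.

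Neighbouring genes shifted together in 17 runs, 11 lower and 6 higher, that held 2168 genes, 16.9% of tested and 31.0% of changed genes. The runs were picked by the same log2 fold changes that gave the calls. An excess inside them of changed genes, and of genes moving the way of the run, therefore follows from the choice. In the run with the most genes, from FAM110C to C2orf55, 85.1% of 376 genes lay below the median of all genes, with a median log2 fold change of -0.32, and in the run from TSPYL4 to PDCD2, 85.6% of 153 lay above it, with a median of 0.35. A chance order of genes is argued against by 0 of 1000 random orders with a window as extreme, and transcript length by the median shift of 0.30 with the length covariate against 0.29 without it. Windows of 21 and 81 genes gave 20 and 16 runs. These held 840 and 3287 genes, and 15.7% and 38.7% of changed genes, so the extent of the runs depends on the window. Runs found from every other gene held 500 genes in between, of which 83.6% moved the way of their run. A candidate explanation is a different copy number of these segments in the ARID1A-deficient cells, by selection of a subclone for example, but no DNA was measured and regulation of whole regions would give the same values.

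The rise of COL1A2, COL3A1 and MGP could come from fibroblasts mixed into the ARID1A-deficient cultures, or from the L3.6pl cells. Fibroblasts would bring their other abundant transcripts, but the median of SPARC, FN1, COL6A1, COL6A2, COL6A3, DCN, LUM and BGN was at most 0.00151 of COL3A1 in any ARID1A-deficient library. That median rests in part on DCN, LUM, BGN and COL6A3 listed at 0, which can be failed estimates, but SPARC was 0.133 to 0.291 FPKM, and COL6A1 and COL6A2 had lower means than in parental cells, at 3.22 against 5.04 and 2.53 against 3.65 FPKM. SPARC and FN1 had higher means than in parental cells, at 0.197 against 0.0129 and 0.462 against 0.238 FPKM. Both stayed far below COL3A1, at 92.9 FPKM. These values argue against fibroblasts, and expression by the cancer cells themselves remains a hypothesis that was not tested.

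Of 14 tested histone genes 8 were higher and of 28 S phase genes 6 were lower, although both kinds are used in S phase, and neither list passed camera with an estimated correlation (adjusted p = 0.177 and adjusted p = 0.11). The counts were 4 and 1 without parental library 3, 3 and 2 without ARID1A-deficient library 2, 3 and 1 without ARID1A-deficient library 3, and 11 and 11 without parental library 2, and 19 S phase genes were lower with the length covariate. Length bias is argued against by lists matched on transcript length and expression, of which 0.01% of 10000 had a median as high as the 0.69 of the histone list, and the median with the length covariate was 0.61. None of the 14 histone genes lies in a shifted run, so their median without run genes is also 0.69, and the S phase list passed camera with the preset correlation without run genes (adjusted p = 0.000230). A larger share of histone transcripts with a poly(A) tail, or reads divided differently among near-identical copies, may also give this pattern; neither was tested.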
